A study of Mus musculus with 2 samples.

How the data were processed

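Liver cells of wild type and Ptpn11 D61G/+ mice on a mixed C57B6x129Sv background were obtained, per the labels' protocols, by flushing the liver, digesting it with collagenase D for 20 min, separating cells in 30% percoll, lysing erythrocytes and sorting CD45 and F4/80 positive cells from a pool of 6 animals per genotype. Libraries were made with a 10x Chromium 3' kit and sequenced on an Illumina instrument, per the labels' protocols. The deposited matrix holds whole-number UMI counts per gene and cell barcode, not normalized, for 27998 genes, with 2103825 entries. Cell Ranger 2.1.0, Seurat 2.0 and the mouse build mm10 are named in the submitters' processing notes, with no role given, and whether the depth of the libraries was equalised when they were combined is not given in the sources used here. Such 3' counts read transcript ends only, and free RNA in the droplets adds a low level of abundant transcripts to every cell.

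The barcodes carry 1 of 2 suffixes. With no key from suffix to genotype, the genotype comparisons that had been planned were not made, and values per suffix are given without genotype. A barcode total ranged from 1036 to 23422 UMIs, with a median of 2142 for suffix 1 and 3133.5 for suffix 2. Cells with at least 200 genes and under 10% mitochondrial UMIs were kept, which removed 78 and 10 barcodes. Scrublet, run per suffix in scanpy 1.11.5, called 7 doublets (0.396% of 1768 cells), and these were removed.

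Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without mitochondrial and ribosomal protein genes and without functional list genes that are not markers, gave 20 principal components, a graph of 15 neighbours and Leiden clusters (igraph 0.11.9) at resolution 0.8 with seed 0. Functional list genes were matched by gene ID, so that Acod1 was found as Irg1. An earlier clustering had matched by symbol only and so kept Irg1. It was looked at first, was replaced because it departed from the planned gene set, and is given among the alternatives. Marker lists (22 lists, 152 of 153 genes matched) and functional lists (22 lists, 358 of 359 genes matched), the cell filter, the clustering settings and the rule for named genes were fixed before the data were examined. A cluster took the name of the class with most markers found in at least 25% of its cells at over 2-fold, with at least 3 such markers, no tie, and no other class with more markers among its top 10 genes. These thresholds of naming were set after the data were seen, and they left 2 of 13 clusters unnamed. Which list counts are treated as main results (at least 10 measured members, most of them higher, or lower for Kupffer cell-like cells) was also settled after the data were seen.

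For each cluster, counts were summed over cells and given as counts per 1000000 UMIs (CPM). The ratio to all other kept cells has an exact conditional 95% interval, a level an exact Poisson interval and a share an exact Clopper-Pearson interval (scipy 1.17.1), all covering counting error only and not the spread between animals. A list member was measured with at least 50 UMIs in all kept cells (7457 genes) and counted as higher or lower when its whole interval lay beyond 1.5-fold. The median log2 ratio of a list, with 0.5 counts added, was ranked among 10000 random lists of the same size matched on expression in 20 bins. Sums weigh deep cells more than shallow ones. The named genes are, for each list, up to 4 members with the highest and lowest ratios beyond 1.5-fold, and the 12 highest and 12 lowest genes between the 2 named macrophage classes with at least 100 UMIs, without mitochondrial, ribosomal, haemoglobin and sex-linked genes, plus Ptpn11. Adgre1, in none of the lists, was added after the data had been seen, and S100a8, Alb, Xist and Ddx3y, members of the lists, are named outside this rule. Kupffer cell-like against other cells was simulated for 7457 genes with Poisson counts, without spread between cells. Intervals held the true value for 94 to 96.1% of genes. These draws follow the model behind the interval, so they check the calculation and not its fit to real cells. The interval lay above 1 for 58% of genes raised 1.5-fold, 87% raised 2-fold and 100% raised 4-fold. The stricter rule of a whole interval beyond 1.5-fold was not used for these shares.

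Alternatives covered clustering resolution, gene number, components, seed, filters, doublets, scaling (TMM in edgeR 4.0.16), equal weight per cell and thinning to 1000 UMIs. Added after seeing the data were the removal of cells over 5% haemoglobin, suffix 2 alone, suffix 1 alone for list counts of classes with at least 20 of its cells, pairs of classes for Ptpn11, Irg1 kept, and clustering of thinned cells. Gene coordinates are from GENCODE M21 on GRCm38; the annotation release of the deposited counts is not given in the sources used here.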

Results

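The study measured gene expression in single cells from the livers of wild type mice and of mice carrying a heterozygous Ptpn11 D61G allele. Ptpn11 encodes the phosphatase SHP2, and this allele is used as a mouse model of Noonan syndrome, a RASopathy. Cells positive for CD45, a pan-leukocyte antigen, and for F4/80, a macrophage antigen, were sorted from a pool of 6 animals per genotype, and 1 droplet library was made per genotype. The study's question was whether the mutation changes liver macrophages. The count matrix held 800 cell barcodes with suffix 1, with 2028694 UMIs (counts of tagged transcript molecules), and 1056 with suffix 2, with 4152502 UMIs. The sources used here give no key from suffix to genotype, so no genotype comparison was made and the matrix was treated as 1 pooled sample. The comparisons below are between cell classes. After filtering, 1761 cells with 6000333 UMIs and a median of 2750 UMIs per cell were kept. There were no replicates and no test, and every 95% interval covers counting error only.

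Monocyte-like cells were the most numerous cells of the sort. A classical monocyte-like cluster, with the markers Ly6c2, Ccr2, Chil3, F13a1 and S100a4, held 354 cells or 20.1% of all kept cells (exact binomial interval 18.3 to 22.1%). A non-classical monocyte-like cluster, with Ace, Spn, Treml4, Cd300e and Ear2 among its 7 markers, held 291 cells or 16.5% (14.8 to 18.3%). Kupffer cells, the resident macrophages of the liver sinusoid, were represented by 178 Kupffer cell-like cells or 10.1% (8.74 to 11.6%), with 11 of 12 markers detected, Clec4f, Vsig4, Timd4, Cd5l and Marco among them. A monocyte-derived or capsular macrophage-like cluster, called macrophage-like from here on, had 141 cells or 8.01% (6.78 to 9.37%) and the markers Cx3cr1, Trem2, Cd63 and Cd207. Cluster 3 held 193 cells, 11.0% (9.54 to 12.5%), was led by Spp1, Fabp5, F10 and Il1rn, and stayed unnamed. Cluster 7 held 112 cells, 6.36% (5.27 to 7.60%), and carried markers of both conventional dendritic cell types (Xcr1, Cd209a) and of proliferating cells (Stmn1). It stayed unnamed because type 1 conventional dendritic cells had most markers detected, 5 against 4 for type 2, but fewer among its top 10 genes. These were Xcr1 for type 1 and Flt3 and Cd209a for type 2. The shares pool 2 unlike libraries, a difference that their intervals do not cover. The classical monocyte-like share was 32.5% in suffix 1 and 10.6% in suffix 2. Within suffix 2 the non-classical monocyte-like (17.9%), Kupffer cell-like (17.3%) and cluster 3 (16.5%) shares were larger. The boundary between the classical monocyte-like cluster and cluster 3 was unstable: the share of the former reached 31.0% without cells over 5% haemoglobin UMIs. In 8 of the 12 other clusterings no unnamed cluster matched cluster 3. A matching cluster that took a name was not counted, so part of this count may come from the naming rule.

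**Figure D1:**
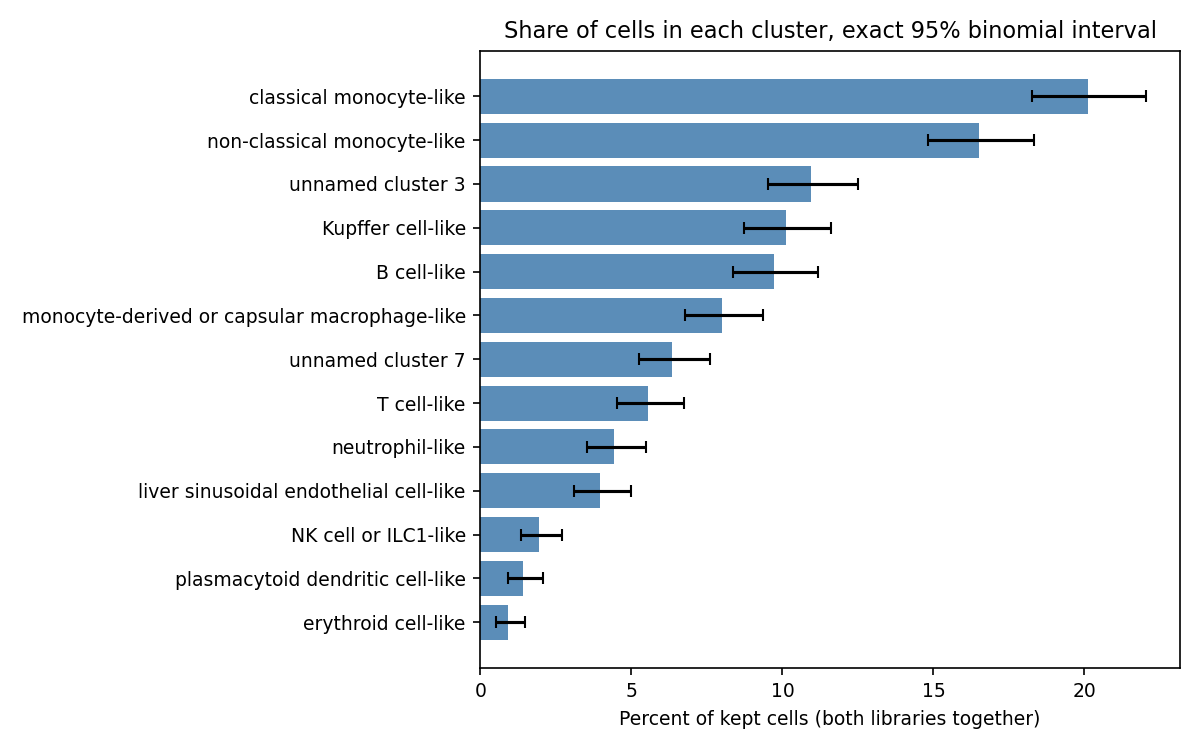
Share of the 1761 kept cells in each of 13 clusters (horizontal axis, percent of kept cells, both libraries together), with exact 95% binomial intervals as whiskers. The classical monocyte-like cluster is highest at 20.1%, and the Kupffer cell-like cluster is at 10.1%. This order is of the pooled cells: within suffix 2 alone these shares were 10.6% and 17.3%.

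Cells outside the mononuclear phagocytes were also present. B cell-like cells (Cd79a, Ms4a1) made up 9.71% (8.37 to 11.2%), T cell-like cells (Cd3e, Cd3d) 5.57% (4.54 to 6.74%), neutrophil-like cells 4.43% (3.52 to 5.50%), liver sinusoidal endothelial cell-like cells (Stab2, Clec4g) 3.98% (70 cells), NK cell or ILC1-like cells 1.93% (1.34 to 2.69%), plasmacytoid dendritic cell-like cells 1.42% (0.921 to 2.09%) and erythroid cell-like cells 0.909% (0.520 to 1.47%). The 5 classes of lymphoid, neutrophil and endothelial cells together came to 451 cells or 25.6% (23.6 to 27.7%). Adgre1, the gene of the sorted antigen F4/80, was at 475 CPM (429 to 524) in Kupffer cell-like cells and 387 CPM (324 to 458) in macrophage-like cells, against 36.5 CPM (17.5 to 67.1) in B cell-like and 4.30 CPM (0.109 to 23.9) in T cell-like cells. An Adgre1 UMI was seen in 80.3% of Kupffer cell-like cells at a median of 4199 UMIs per cell, and in 1.02% of T cell-like cells at a median of 2156. Of the Kupffer cell-like cells, 173 carried suffix 2 and 5 suffix 1.

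Kupffer cell-like cells had higher complement, iron and heme, scavenger receptor and lysosomal genes than other cells. Of 13 measured complement genes, 11 were over 1.5-fold higher than in all other cells and 1 was lower. C4b (GRCm38, chromosome 17, 34728380 to 34743882) reached 432 CPM against 12.7 CPM, a ratio of 33.9 (26.0 to 44.8), and C1qc, a chain of the C1q initiator of the classical pathway, 5797 against 423 CPM, a ratio of 13.7. C3 was lower, with a ratio of 0.243 (0.145 to 0.383). Among 13 iron and heme genes, 11 were higher and 1 lower. Slc40a1, the iron exporter ferroportin, had a ratio of 36.2 (31.7 to 41.5), Spic, a transcription factor of iron-recycling macrophages, 13.4 (8.39 to 21.8), and Hmox1, which degrades heme, 10.2 (9.18 to 11.4). The haptoglobin gene Hp was the lower member at 0.122 (0.0864 to 0.167). Scavenger and phagocytic receptors were higher for 16 of 20 members. Markers used to name classes are 5 of these 20, 2 complement genes, 2 iron genes (Slc40a1 among them) and the lysosomal Cd63. Fcgr2b, an inhibitory Fc receptor, was lower with a ratio of 0.214 (0.144 to 0.308). Lysosomal genes were higher for 14 of 22 members, Lgmn at 7.18 (6.72 to 7.66) and Ctsb at 5.05 (4.86 to 5.26) among them, with Cd63 lower at 0.123 (0.0529 to 0.245). The lysosomal rise was not particular to this class, since 6 members were higher in cluster 3 and 5 in macrophage-like cells. The median log2 ratio was 3.34 for complement, 2.14 for iron and heme, 2.23 for scavenger receptors and 0.99 for lysosome, each above all 10000 expression-matched random lists, against 0.09 for the median of all genes. The markers were left in for these medians and ranks. Within suffix 2 alone the numbers higher were 11 for complement and 11 for iron and heme genes, the complement median was 2.97 and the ratio of C4b was 22.8.

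Lipid genes went both ways in these cells, with 10 of 22 members higher and 5 lower. Fabp7, a fatty acid binding protein, had a ratio of 62.3 (53.1 to 73.5), Apoc1 21.3 (19.8 to 22.9) and Abca1, a cholesterol exporter, 9.51 (6.66 to 13.7). Fabp5 was lower at 0.185 (0.114 to 0.285) and Cd9, a member of the macrophage marker list, at 0.131 (0.0862 to 0.192). Chemokine genes split as well, 5 of 16 higher and 7 lower. Cxcl13, a B cell attractant, had a ratio of 58.1 (35.7 to 101), which was 36.4 within suffix 2, and Cxcl14 13.2 (10.9 to 16.2), while Ccl4 was at 0.127 (0.103 to 0.156) and Ccl5 at 0.132 (0.0968 to 0.176). Type I interferon response genes were higher for 5 of 20 members, led by Irf7 at 801 against 181 CPM and Rtp4 at 2.58 (2.18 to 3.04). Within suffix 2 that count was 3 and the list median fell from 0.61 to 0.37.

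Immediate early and inflammatory genes were low in Kupffer cell-like cells. Of 22 genes of the dissociation and immediate early response, which tissue digestion is known to induce, 17 were over 1.5-fold lower than in other cells and 2 higher. Fosb had a ratio of 0.0776 (0.0311 to 0.161), Egr1 0.107 (0.0631 to 0.170) and Atf3 0.156 (0.112 to 0.212), and the chaperone genes Hsph1 at 2.11 (1.51 to 2.92) and Hspe1 at 1.74 (1.57 to 1.92) were the higher members. Within suffix 2 alone 15 members were lower, with Fosb at 0.159 and Egr1 at 0.256. Pro-inflammatory genes were lower for 9 of 15 members, Socs3 at 0.126 (0.0571 to 0.241) and Tnfaip3 at 0.215 (0.102 to 0.401) among them, and the costimulatory gene Cd86 was higher at 2.80 (2.21 to 3.53). MHC class II genes were lower for 7 of 11 members, H2-DMb2 most at 0.116 (0.0464 to 0.242), and Ctss was higher at 2.29 (2.20 to 2.39). With cells thinned to 1000 UMIs the pro-inflammatory count was 4 and the MHC class II count 2, and with each cell weighted equally the MHC class II count was 3. Within suffix 2 the MHC class II count was 10, while among the 5 cells of suffix 1 there were 4 MHC class II genes higher and 0 lower.

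Classical monocyte-like cells had the opposite profile for immediate early genes, 17 of 22 of which were over 1.5-fold higher than in other cells and 2 lower. Fos, an AP-1 subunit (chromosome 12, 85473890 to 85477273), reached 2415 CPM against 659 CPM, a ratio of 3.66 (3.49 to 3.85), followed by Fosb at 3.29 (2.78 to 3.88) and Atf3 at 3.25 (2.96 to 3.58). Of the cells, 248 carried suffix 1 and 106 suffix 2, and the count was 9 of 22 within suffix 2 alone and 6 of 22 within suffix 1 alone, where the ratio of Fos was 2.34 and that of Fosb 1.77. Fn1, the fibronectin gene, had a ratio of 14.0 (12.4 to 16.0), while 9 of 11 MHC class II genes were lower, H2-Oa at 0.0823 (0.0352 to 0.164) and H2-Eb1 at 0.148 (0.139 to 0.159). Non-classical monocyte-like cells had 13 of 16 chemokine genes and 14 of 20 type I interferon genes lower, Usp18 at 0.182 (0.0490 to 0.472) among them. These counts were 12 and 12 within suffix 2 and 5 and 1 within suffix 1, where the class had 112 cells against 179. The median log2 ratio of the chemokine list was -2.19 within suffix 2 and -1.57 within suffix 1. For the type I interferon list it was -1.36 and -1.29. In cluster 3, 12 of 20 type I interferon genes were higher and none lower by over 1.5-fold. Isg15 had a ratio of 3.43 (3.05 to 3.84) and Ifit3 3.32 (2.55 to 4.30). The interferon gamma targets Cxcl9 at 309 against 25.6 CPM and Gbp2 at 8.09 (5.85 to 11.2) and the glycolytic gene Tpi1 at 2.42 (2.08 to 2.80) were also higher there. With cells thinned to 1000 UMIs, 7 of the type I interferon genes were higher in cluster 3, and the count was 10 within suffix 2 and 3 within suffix 1, which held 28 of its cells. In suffix 1 the ratio of Ifit3 was 1.92. The median log2 ratio of the type I interferon list in cluster 3 was 1.24 within suffix 1 and 1.09 within suffix 2.

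Macrophage-like cells carried high MHC class II transcripts, with 7 of 11 genes over 1.5-fold higher than in other cells and none lower. H2-Eb1 had a ratio of 4.93 (4.78 to 5.09), H2-Ab1 3.54 (3.44 to 3.65) and Cd74, the invariant chain, 3.44 (3.38 to 3.50). Of 16 chemokine genes 6 were higher, Ccl4 at 10.7 (10.1 to 11.3) and Cxcl16 at 6.02 (5.03 to 7.18) among them, and 3 lower. Within suffix 2 the ratio of Ccl4 was 6.99, and within suffix 1 that of H2-Ab1 was 5.65 and that of Cxcl16 12.8. Cluster 7 had 10 of 11 MHC class II genes higher, H2-Oa at 9.04 (7.24 to 11.3), and all 14 measured cell cycle genes higher, Rrm2 at 20.1 (11.8 to 36.1) and Ccna2 at 19.6 (10.1 to 41.1); 5 of these 14 are also markers. Within suffix 1 the ratios were 4.797 for H2-Oa, 9.52 for Rrm2 and 11.9 for Ccna2. Neutrophil-like cells had 10 of 15 pro-inflammatory genes higher. Irg1 had a ratio of 48.3 (33.3 to 70.7), Ptgs2 20.8 (15.5 to 27.9) and Il1b 17.5 (16.0 to 19.2), and the values for Irg1 and Ptgs2 were 73.2 and 36.4 within suffix 2 and 26.0 and 7.04 within suffix 1. The count was 10 within suffix 2 and 5 within suffix 1.

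**Figure D2:**
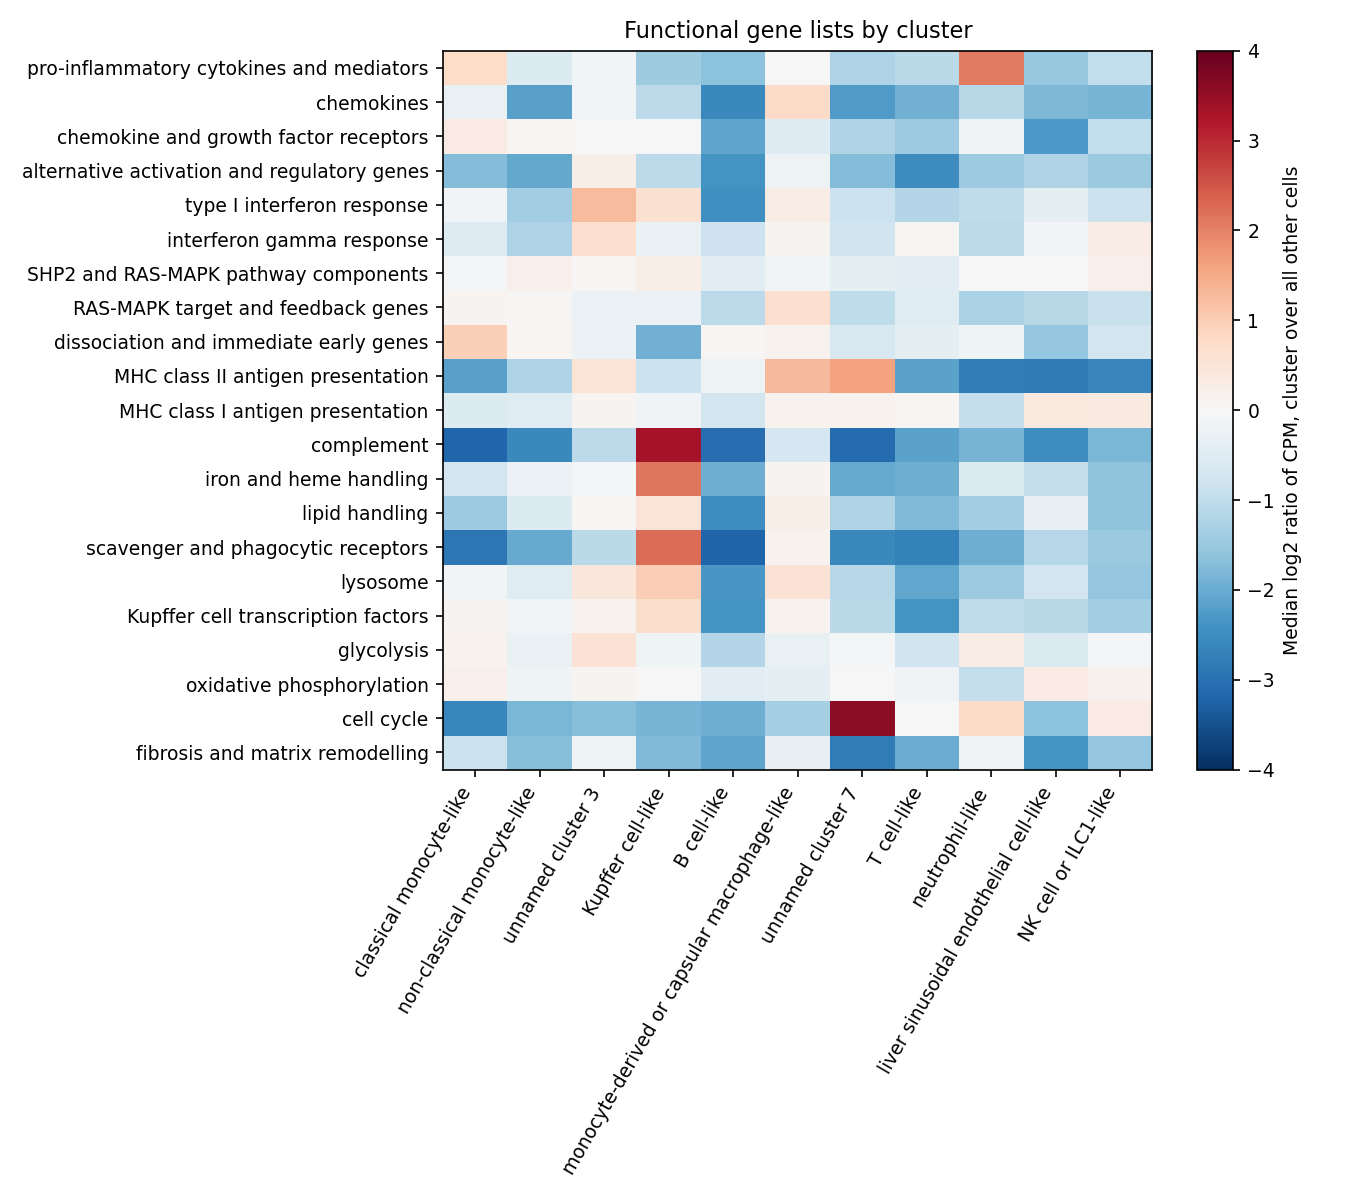
Median log2 ratio of CPM (colour) for the functional gene lists (vertical axis) in each cluster of at least 30 cells against all other kept cells (horizontal axis). The Kupffer cell-like column is highest for complement at 3.34, and cluster 7 for cell cycle at 3.58.

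Marco, Fabp7, Vsig4 and Fcna were far higher in Kupffer cell-like than in macrophage-like cells, and Ccl4, Cd63, Ccl3 and Egr1 far lower. Among 1354 genes with at least 100 UMIs over both classes, those highest in Kupffer cell-like cells by the plain ratio were Pcolce2, Marco, Fabp7, Tspan15, Paqr9, Vsig4, Cdh5, Cd163, Fcna, C6, Folr2 and Cd5l. Pcolce2 had 110 UMIs against 0, which is 15.4-fold higher against a floor of 3 counts over the class. The exact lower limit of its ratio was 12.3. The places of Pcolce2, Tspan15 and Paqr9 rest on 0 or 1 UMI in macrophage-like cells and would be lower with that floor. Marco, a scavenger receptor (chromosome 1, 120474538 to 120505024), was at 792 against 8.72 CPM, a ratio of 90.7 (30.9 to 441), Fabp7 had a ratio of 69.5 (37.7 to 145), Vsig4, a complement receptor, 40.1 (24.2 to 71.8), and Fcna, a ficolin, 35.9 (24.0 to 56.1). The genes highest in macrophage-like cells were Ccl4, Cd63, Mmp12, Ccl3, Egr1, Cx3cr1, Clec4b1, Ccr2, Ppp1r15a, Nfkbiz, Cd9 and Slamf9. Ccl4 (chromosome 11, 83662584 to 83664683) was at 5403 CPM against 114 CPM, 47.5-fold higher (38.6 to 59.1), Cd63 33.6-fold (16.5 to 79.7), Egr1 21.7-fold (13.3 to 37.5), and Cx3cr1, the fractalkine receptor, 13.7-fold (8.45 to 23.2). Of these 24 genes 13 were among those used for clustering and 11 were markers, so part of the difference defined the classes. Within suffix 2 the ratio was 57.8 for Marco, 44.0 for Fabp7 and 23.8 for Fcna, and the macrophage-like excess was 28.1-fold for Ccl4 and 10.1-fold for Egr1.

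By gene group, macrophage-like cells had the higher level for 13 of 20 immediate early genes, 6 of 7 MHC class II genes, 7 of 13 chemokine genes, 4 of 7 pro-inflammatory genes and 4 of 10 RAS-MAPK target and feedback genes, each beyond 1.5-fold. The other way went 1 immediate early and 3 chemokine genes. Kupffer cell-like cells had the higher level for 8 of 13 iron and heme genes, 8 of 18 scavenger receptors, 5 of 11 complement genes and 5 of 21 lysosomal genes, against 1 scavenger receptor and 2 lysosomal genes higher in macrophage-like cells. No interferon gamma, MHC class I, glycolysis or SHP2 and RAS-MAPK pathway gene, out of 4, 11, 10 and 9 measured members, had a whole interval beyond 1.5-fold, though some, such as Aldoa at 1.56 (1.23 to 1.99), had an interval above 1.

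**Figure D3:**
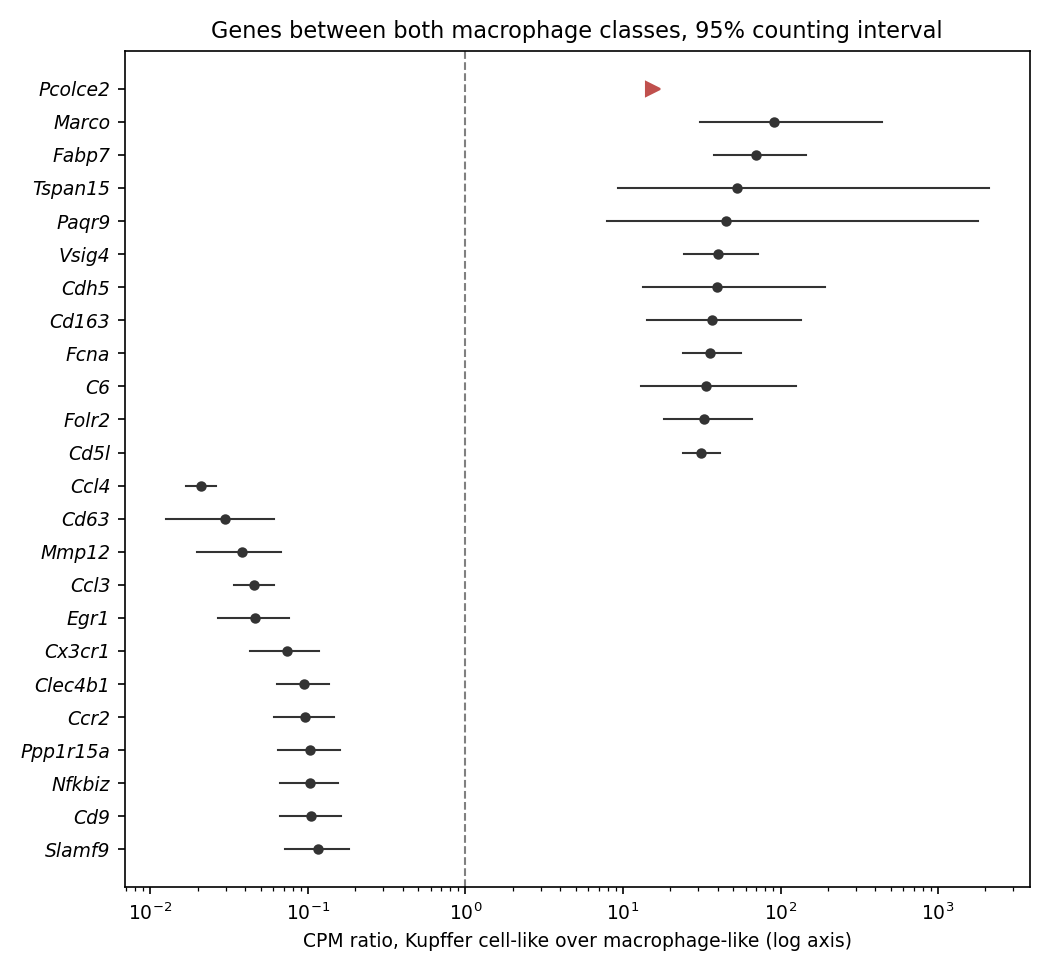
Ratio of CPM, Kupffer cell-like over macrophage-like cells (log axis), for the 12 highest and 12 lowest genes, with 95% counting intervals as lines. The triangle for Pcolce2 is a lower bound of 15.4, and the ratio of Marco is 90.7.

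Ptpn11, the mutated gene (ENSMUSG00000043733, chromosome 5, 121130533 to 121191397, minus strand), was detected at a low level in most classes. Over all kept cells it had 160 UMIs, 26.7 CPM (22.7 to 31.1). The level was 30.6 CPM (19.8 to 45.2) in Kupffer cell-like, 40.7 CPM (22.3 to 68.3) in macrophage-like, 43.7 CPM (28.8 to 63.6) in non-classical monocyte-like and 17.7 CPM (11.4 to 26.4) in classical monocyte-like cells. Over the 6 pairs of these classes, compared with the exact conditional interval of the ratio, classical monocyte-like cells were lower than non-classical monocyte-like cells, which had 2.46 times their level (1.37 to 4.46), and lower than macrophage-like cells, which had 2.29 times (1.10 to 4.62). For the other 4 pairs a difference was not detectable at this depth. The 2 differences rest on 24 UMIs in classical monocyte-like, 27 in non-classical monocyte-like and 14 in macrophage-like cells. Intervals were not adjusted for the 6 pairs, which were chosen after seeing the data. No pair was recomputed per library or in another clustering. Of 20 measured SHP2 and RAS-MAPK pathway genes, 0 in classical monocyte-like, 2 in non-classical monocyte-like, 1 in Kupffer cell-like and 0 in macrophage-like cells had a whole interval beyond 1.5-fold of the other cells. In endothelial cell-like cells 4 were higher and 1 lower, but 0 were higher within suffix 2 and 1 within suffix 1, and the list median of -0.01 lay under the 0.26 of all genes. A point mutation is not visible in a gene count, so these levels do not check the genotype labels.

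**Figure D4:**
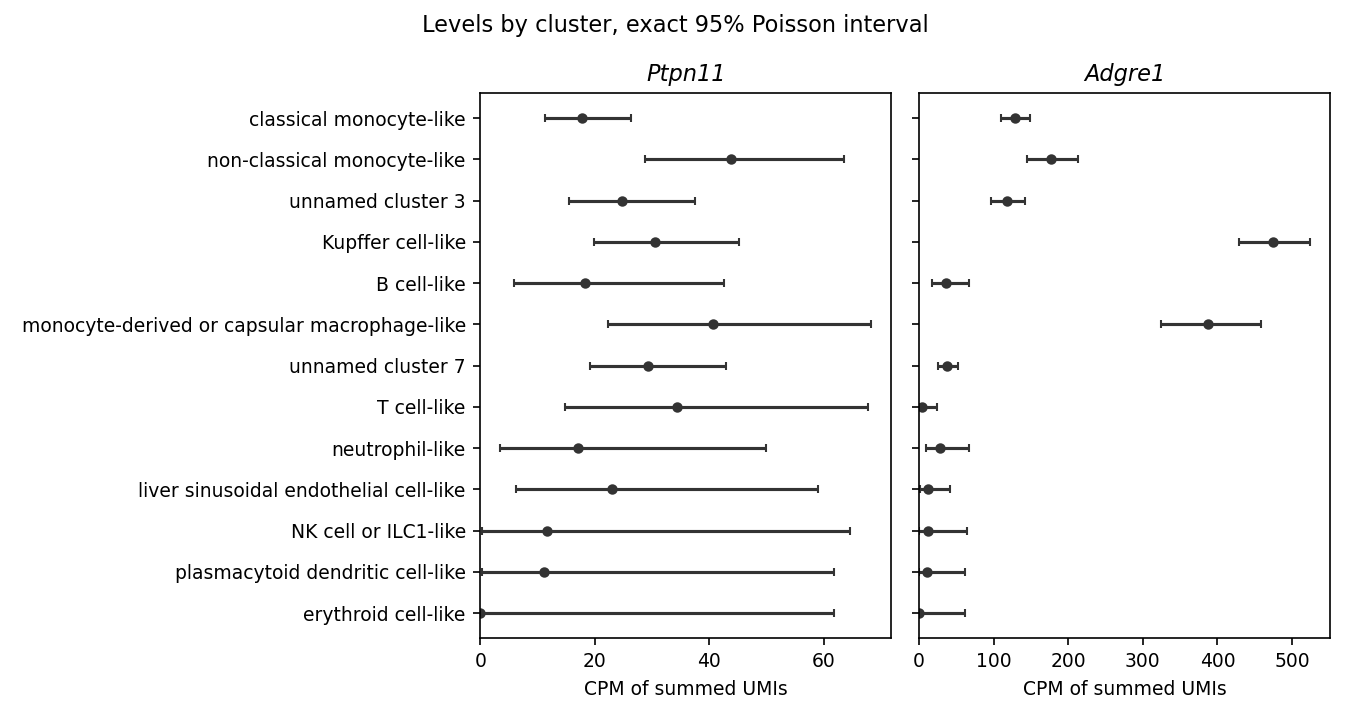
CPM of summed UMIs of Ptpn11 (left) and Adgre1 (right) in each cluster, with exact 95% Poisson intervals as whiskers. Adgre1 is highest in Kupffer cell-like cells at 475 CPM, and the Ptpn11 intervals of most clusters overlap.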

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

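The test of depth on the Kupffer cell-like share was set before its result was seen, and the other tests of this part were chosen after related values had been seen. The key from suffix to genotype being absent from the sources used here, genotype stays open and untested for each pattern.

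Signals in data that the comparisons do not use are given first. The 78 barcodes removed for under 200 genes had a median of 92.6% haemoglobin UMIs. Kupffer cell-like cells were 17.3% of suffix 2 cells (173 of 998) and 0.655% (0.213 to 1.52%) of suffix 1 cells. B cell-like cells were 17.2% (14.6 to 20.0%) of suffix 1 and 4.01% (2.88 to 5.42%) of suffix 2.

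The Kupffer cell-like gap between the libraries was weighed against 3 technical explanations. Lower depth of suffix 1 is argued against, since after thinning every cell to 1000 UMIs and clustering again the share in suffix 2 was still 18.8 times that in suffix 1 (17.2% against 0.917%). Misplacement in other clusters is argued against by markers, since 1.05% (0.454 to 2.06%) of suffix 1 cells in any cluster had UMIs of at least 3 of Clec4f, Cd5l, Vsig4, Marco, Timd4 and Folr2, 3 of these cells outside the class. The rule is a loose one, which 123 of the 825 suffix 2 cells outside the class also met, through free RNA or otherwise. Breakage in the loaded suspension is argued against, since these 6 transcripts summed to 12.5 CPM (4.04 to 29.1) in lymphocyte-like and neutrophil-like cells of suffix 1 and 680 CPM (598 to 769) in those of suffix 2. A loss of Kupffer cells before loading, a different sort gate, or the genotype could each give the gap and none was tested.

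Immediate early genes were higher in suffix 1. A response to handling shared by every cell type may account for it: the list median of suffix 1 over suffix 2 was above that of all genes in 9 of 9 classes with at least 20 cells in each library, by 0.23 to 1.10 on the log2 scale. Other lists were also shifted between the libraries, though some of their offsets were near 0. RAS-MAPK target and feedback genes, which share 2 members with the immediate early list, were also above in 9 of 9 classes, by 0.06 to 0.81. That overlap counts identical genes only. The full list also holds other early response genes, such as Dusp1, so its shift is not a separate sign of that pathway. Pro-inflammatory genes, which share 1 member with the immediate early list, were above in 8 (range -0.53 to 1.22). Type I interferon genes (-1.63 to 0.21) and MHC class II genes (-1.88 to 0.23) were each below in 8. Oxidative phosphorylation genes were below in 9 (-0.33 to -0.02). Handling, free RNA and genotype therefore stay open. The excess of these genes in classical monocyte-like over other cells had a median log2 ratio of 0.96 over both libraries, 0.63 within suffix 2 and 0.45 within suffix 1. Library make-up may give part of it, but not the whole, since it stayed above 0 within each library.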

How the results depend on the processing

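The alternatives without cells over 5% haemoglobin, with Irg1 kept, within suffix 2, within suffix 1 and with thinned cells clustered again were chosen after seeing the data. Of 130 recomputed class shares 109 stayed within the interval of the reported share. Of 217 list counts, which cover 20 results, 205 stayed within 1.5 times. Of 240 ratios of the 24 genes between Kupffer cell-like and macrophage-like cells, 234 stayed within their interval, 6 moved and 0 changed direction. Those 6 were Fcna, Ccl4, Ccl3 and Egr1 within suffix 2 and Mmp12 and Ccr2 after thinning. The 24 genes were picked as the most extreme of these data, the least of them 8.65-fold apart. A change of direction was therefore unlikely from the start, and these counts are a weak check. The macrophage-like class was not formed with functional lists kept or with 10 components, where these ratios were not recomputed. Gene ratios of a class over other cells and other list counts are not in these totals. Several of them left their interval or fell within 1 library, as given above. The Kupffer cell-like share stayed between 9.89 and 10.6% in all clusterings, which made 9 to 15 clusters. The classical monocyte-like share was 14.2% with functional lists kept, 23.3% with 10 components, 28.9% with doublets kept, 23.2% without cell filter, 25.8% at 500 genes or more, 22.8% with seed 1, 31.0% without cells over 5% haemoglobin and 14.4% with Irg1 kept. Cluster 3 was at 6.76% with 10 components, 9.09% with 30 and 17.5% with Irg1 kept. The non-classical share was 14.7% and the macrophage-like 10.1% with 1000 variable genes, cluster 7 9.09% with 30 components, T 7.33% with 10 components, and B 8.23% and neutrophil 3.43% at 500 genes or more. A larger cluster took the erythroid name with doublets kept (2.88%), at 500 genes (6.28%) and with seed 1 (8.97%). The erythroid share was 4.92% without filter, where the 78 barcodes of under 200 genes, all over 80% haemoglobin, were let back in. The reported 0.909% leaves such barcodes out. Classes not formed in a clustering have no value there, nor does cluster 3 or 7 where a matching cluster took a name. The immediate early count in classical monocyte-like cells was 9 with equal weight per cell, 8 thinned, 11 with doublets kept, 11 without cells over 5% haemoglobin 9 in suffix 2 and 6 in suffix 1. In suffix 1 the type I interferon count of cluster 3 was 3 and the pro-inflammatory count of neutrophil-like cells 5. Thinned, the type I interferon count of cluster 3 was 7, and in Kupffer cell-like cells the lower counts were 4 for pro-inflammatory and 2 for MHC class II genes (3 with equal weight per cell). Ptpn11 was at 35.9 CPM without mitochondrial, ribosomal and haemoglobin genes, by the smaller total. For the other moved values the cause was not tested. Leaving those genes out of the total shifted the median gene by -0.19 in Kupffer cell-like, 0.39 in B, 0.34 in T, -0.30 in neutrophil-like and -0.11 in macrophage-like and endothelial cell-like cells (log2). TMM shifted it by -0.13 in Kupffer cell-like, 0.12 in B, 0.39 in neutrophil-like, -0.50 in endothelial, -0.32 in NK, -0.38 in plasmacytoid dendritic, 1.33 in erythroid (2.21 without those genes) and 0.10 in classical monocyte-like cells. List counts are relative to the plain total. TMM was not run for the Ptpn11 level, where 1 pooled sample has no factor, and genotype alternatives were not run.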

Other observations

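Other gene groups and classes held further differences, all from counts with no replicate. T cell-like cells had 4 of 13 MHC class I genes over 1.5-fold higher than other cells, the nonclassical genes H2-Q7 at 5.33 (4.30 to 6.57) and H2-Q6 at 4.41 (3.05 to 6.22) first. In B cell-like cells the class II modulators H2-Ob at 10.9 (8.36 to 14.2) and H2-DMb2 at 10.6 (8.52 to 13.1) were higher and Ctss lower at 0.274 (0.232 to 0.321). Endothelial cell-like cells had the receptor genes Lyve1 at a ratio of 340.1 (157 to 877), Stab1 at a ratio of 42.4 (35.3 to 51.0) and Mrc1 at 20.4 (16.8 to 24.6), the last pair at 73.5 and 42.2 within suffix 1, and the respiratory chain genes Ndufa4 at 2.14 (1.80 to 2.53) and Cox7a2 at 1.83 (1.53 to 2.18), where the median log2 ratio of all genes was 0.26. The hepatocyte gene Alb was also higher in these cells, at 725 against 15.8 CPM, a ratio of 45.9 (34.8 to 60.8). The ratio was 6.41 within suffix 1 and 56.2 within suffix 2. Its 126 UMIs came from 15.7% of these cells, a spread between cells that the interval does not cover. An Alb UMI was seen in 1.02% of T cell-like cells, at median depths of 2237 and 2156 UMIs. In Kupffer cell-like cells, the next highest class, the share was 10.7% at a median of 4199 UMIs. In macrophage-like cells 5 of 13 complement genes were higher and 6 lower. The median log2 ratio was -0.66 over both libraries, -0.88 within suffix 2 and 1.72 within suffix 1. Among these genes C3ar1, a complement receptor, was at 5.23 (3.86 to 6.99) and C1qb at 3.93 (3.74 to 4.13), while C3 was at 0.0641 (0.00775 to 0.233). C3ar1 and C1qb were at 3.70 and 3.03 within suffix 2 and 41.0 and 33.7 within suffix 1. Kupffer cell-like cells, high in complement genes, were 173 of the other cells in suffix 2 and 5 in suffix 1. The ratios per library thus have unlike comparators, and a difference of the macrophage-like cells themselves was not tested.

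Each library's other values are given without genotype. The suffix 2 to suffix 1 ratio of shares was 0.733 (0.519 to 1.03) for macrophage-like, 1.22 (0.960 to 1.56) for non-classical monocyte-like and 0.327 (0.258 to 0.412) for classical monocyte-like cells. Cluster 3, whose boundary with the last class was unstable, went the other way at 4.51 (3.01 to 6.99), with 165 of its 193 cells in suffix 2, and both classes pooled gave 0.751 (0.632 to 0.891). The ratio was 2.48 (1.09 to 6.35) for NK cell or ILC1-like cells, and cluster 7 was 3.67% (2.45 to 5.26%) of suffix 1 and 8.42% (6.77 to 10.3%) of suffix 2. Xist had 0 UMIs in both libraries, where a floor of 3 counts is 1.53 CPM in suffix 1 and 0.743 CPM in suffix 2 and the exact upper bounds are 1.88 and 0.913 CPM, and the Y-linked Ddx3y was at 61.7 CPM (51.2 to 73.7) and 59.4 CPM (52.2 to 67.4). Ptpn11 was at 25.5 CPM (18.9 to 33.6) in suffix 1 and 27.2 CPM (22.4 to 32.8) in suffix 2. The neutrophil gene S100a8 was at 1234 CPM in classical monocyte-like and 893 CPM in Kupffer cell-like cells against 139300 CPM in neutrophil-like cells.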
